A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

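RNA of the monosome and the polysome fraction was sequenced from shoots of rice seedlings of the wild type (WT) and of the osfkbp20-1b mutant (KO), with 3 libraries in each of 4 groups. All 12 libraries came from seedlings grown for 3 days on gel and 4 days in tubes and then kept in 20% PEG-6000 for 6 hours, per the labels' protocols. The labels describe rRNA depletion before library construction. No source used here says whether the replicates were separate plantings, so the p-values measure only the spread between these samples.

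Per the submitters' processing notes, HTSeq and DESeq were used on the build IRGSP-1.0, with no version and no role given for either tool. The authors deposited 1 full table per fraction, with 349605 exon and intron entries of 44667 transcripts on 12 nuclear chromosomes. Per the file headers, its values per library are a signal called normalized count. Every such deposited value was a whole multiple of the lowest value of its library within a relative tolerance of 1e-06, which held for 100% of values in all 12 libraries. Exons that span an annotated retained intron were used to find what the lowest value stands for. In 453 of 453 library values where the other parts were at the lowest value, the spanning exon equalled the remaining part, which fits 1 read added to each count before scaling. Whole reads were therefore recovered as the value divided by the lowest value, minus 1. The deposited raw counts of OsUBQ3 equalled the recovered reads plus 1 of its exon in 12 of 12 libraries.

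Per the file headers, the authors' retention ratio divides the intron value by the mean of the neighbouring exon values, and the group means given are means over 3 libraries. The deposited ratio of the group means is the larger over the smaller, so it has no direction of its own. The deposited p-value is unadjusted, and the test behind it is not named in the sources used here. In both fractions it equalled a two-sided Welch t-test on the ratios per library for 100% of introns where that test gave a value. A shorter table per fraction marks the introns that the authors selected. The rule p under 0.05, ratio of at least 1.5 and a highest normalized count of at least 20 returned 180 of 180 selected monosome introns and 100 of 100 selected polysome introns, and no other intron. A further table holds raw counts, normalized values and the authors' log2 fold changes of 3 housekeeping genes. The log2 fold changes were not used, and of 72 columns named for single libraries over all files, 48 were not used: they repeat values of the full tables, follow from them as ratios per library, or are scaled copies of the raw counts.

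The full tables were joined by position, and each intron or exon listed for several transcripts was used in 1 copy for library totals. Retention per library was log2 of intron reads plus 1 over the mean reads of the neighbouring exons plus 1. An intron was tested when it and the mean of its neighbouring exons each had at least 10 reads in at least 3 of the libraries compared. Gene abundance was the sum of exon reads of 1 transcript per locus, the one with most exon reads, filtered with filterByExpr, scaled by TMM and expressed as log2 CPM with a prior of 1 read. Fold changes are on these scales, which understate the change of low features. Strand use in counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated.

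KO and WT were compared within each fraction with limma (limma 3.58.1, trend, two-sided) and Benjamini-Hochberg adjustment at 0.05. The plan named a count test for paired intron and exon counts, but because the files hold a scaled signal, the branch for normalized values was used and the count tests on recovered reads became alternatives: edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. The difference of the KO effects between fractions was tested in 1 model over all 12 libraries, and the reads recovered from both tables undo their scaling, so library size is the remaining difference. Group values with 3 against 3 libraries were compared with two-sided exact permutation tests, whose smallest p is 0.1. Overlaps were tested with Fisher's exact test. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

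A total of 19 gene lists were fixed by words in the deposited gene descriptions before the data were examined: SR proteins, spliceosome components, FK506-binding proteins and cyclophilins, abscisic acid signalling, LEA proteins and dehydrins, DREB, NAC and heat stress factors, osmolyte synthesis, heat shock proteins and chaperones, antioxidant enzymes, aquaporins, cytosolic ribosomal proteins, translation factors, photosynthesis, mRNA decay and exon junction complex, circadian clock, calcium signalling kinases, seed storage proteins, root markers, and plastid or mitochondrial genes. Reading the descriptions showed 149 wrong word matches, 100 of them in the mRNA decay list and 42 in the seed storage list, which were dropped before any list was tested. The NAC list keeps subunits of the nascent polypeptide-associated complex, the ribosomal list keeps some plastid-type proteins, and the chaperone list keeps a metal chaperone and a malate transporter family member. The photosynthesis list keeps a ferredoxin-nitrite reductase. The lists hold 1513 genes, 18 of them in more than 1 list, and the plastid or mitochondrial list is empty because the tables hold nuclear chromosomes only. Lists were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) with fry beside it, adjusted over the lists of a comparison.

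Before the data were examined, the introns to be named were set as the 10 largest changes per direction past the adjusted threshold, with no overlap between groups and at least 10 mean reads, or, with none past it, the 10 with the smallest p, and up to 3 per list. The same rule for genes and for the authors' selected introns was set after the data were seen. The 8 monosome genes past the threshold but outside the rule are treated as chosen after their values were seen. Fold changes against a group with 0 reads use a floor of 3 reads over the group. Intervals and floors cover counting error only.

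On simulated counts with the means and depths of these libraries, the tests recovered 45.3% of 4-fold intron changes in the monosomes and 73.5% in the polysomes, with 0% and 1.79% of 2-fold changes. For genes, they recovered 93.5% and 96.7% of 4-fold changes and 14.1% and 53.2% of 2-fold changes, in the monosomes and the polysomes. The simulation gave all features of a comparison 1 common spread and the neighbouring exons counting error only. It held no mixed or outlying library, so these shares need not hold for the real libraries. Alternatives varied the tool, the scaling, the filter, the pseudocount, the threshold, the samples in the fit and the block, and left out each library in turn. The library columns are numbered P1 to P3 in the monosomes, P2 to P4 in polysome WT, and P2, P3 and P5 in polysome KO, which are not the replicate numbers of the titles, so columns were assigned to groups only. No pairing of OsFKBP20-1b with an identifier was found: 0 identifiers matched the table of rice gene names, whose assembly differs, so the targeted gene was not examined here.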

Results

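The data are 12 RNA-seq libraries from shoots of 1-week-old rice seedlings (Oryza sativa Japonica Group, cultivar ZH11) kept in 20% PEG-6000, an osmotic agent used to mimic drought, for 6 hours. Sucrose gradients separated mRNA bound to monosomes, which are single ribosomes, from mRNA bound to polysomes, which are several ribosomes on 1 transcript. Each fraction was sequenced from the WT and from the osfkbp20-1b mutant (KO), a mutant in a gene of the FK506-binding proteins, with 3 libraries in each of 4 groups. All plants received PEG, so the comparisons are between genotypes under osmotic stress and do not address the stress itself. Recovered reads ranged from 9117787 to 13398564 in monosome WT, from 12447430 to 15118912 in monosome KO, from 14535913 to 20812911 in polysome WT and from 14965534 to 21322408 in polysome KO. The targeted gene was not examined here, since the sources used here do not pair it with an identifier. Libraries are named as labelled. The libraries labelled polysome WT P2 and P3 are in doubt, for the reads described with the polysome genes.

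The first question, set by the title's interest in alternative splicing, was whether the mutant carried more intron sequence on its ribosomes. Intron reads made up 3.83% ± 0.255 of reads in monosome KO and 4.49% ± 0.832 in monosome WT (SD, n = 3). They made up 2.89% ± 0.121 in polysome KO and 2.97% ± 0.213 in polysome WT (SD, n = 3). Neither difference passed the test (exact permutation p = 0.4 in the monosomes and 0.5 in the polysomes). With the Rubisco copies described next left out of the totals, the differences were -0.364 percentage points in the monosomes and -0.400 in the polysomes (exact permutation p = 0.8 and 0.2). The library labelled monosome WT P1 had 5.26% intron reads (95% Wilson interval 5.25 to 5.28), and without it the monosome difference was -0.268 percentage points in place of -0.654, while without monosome WT P2 it was -1.09. Without the library labelled polysome WT P4 the polysome difference was 0.0290 in place of -0.0752. Annotated copies of the Rubisco large subunit gene on nuclear chromosomes took the largest part of all reads. They held 46.0% ± 1.91 in monosome KO and 39.7% ± 1.52 in monosome WT, with every KO library above every WT library (SD, n = 3, exact permutation p = 0.1, the smallest possible). In the polysomes they held 24.0% ± 6.72 in KO and 29.6% ± 1.72 in WT (SD, n = 3, exact permutation p = 0.2), where the library labelled polysome KO P5 stood at 16.2% (95% Wilson interval 16.2 to 16.3). Without it the polysome difference was -1.74 percentage points in place of -5.61. These copies resemble the plastid gene, so the origin of their reads is uncertain.

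**Figure D1:**
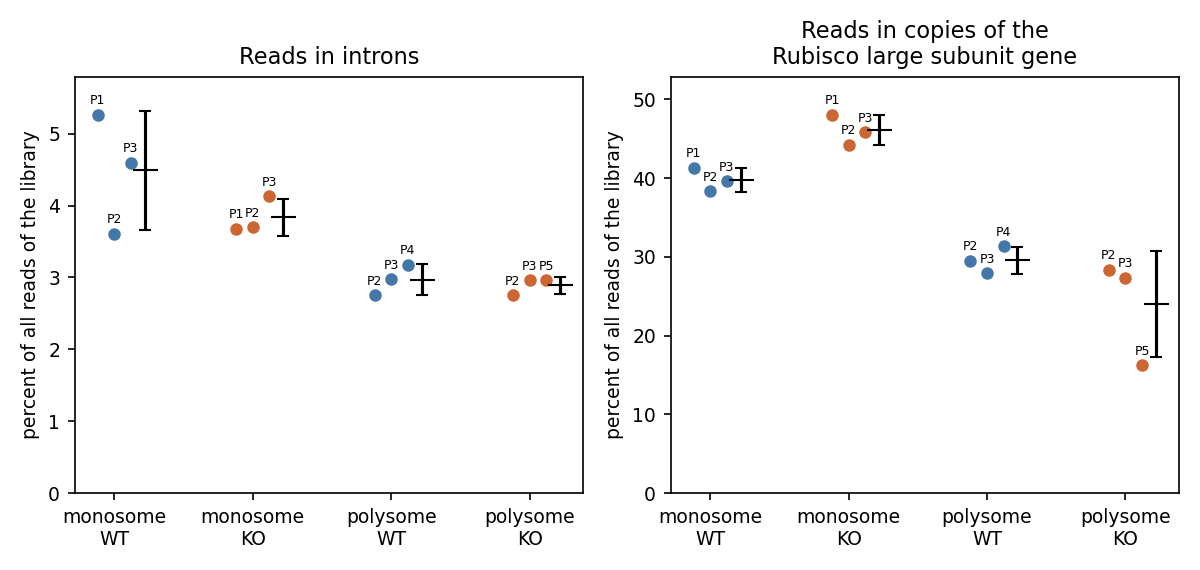
Reads in introns (left) and in nuclear copies of the Rubisco large subunit gene (right), as percent of all reads of a library, for 4 groups; points are libraries with their column number, black bars the mean ± SD of 3 libraries. Monosome KO lies above monosome WT for the Rubisco copies, at 46.0% and 39.7%, and the intron shares of KO and WT overlap in both fractions.

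In the monosomes, the question was which introns were retained more or less often in the mutant relative to their neighbouring exons. Intron 1 of Os04t0587451, a non-protein-coding transcript on chromosome 4 (29666750 to 29670245, IRGSP-1.0), rose in KO by 5.80 on the log2 scale (SE 0.607, limma adjusted p = 0.0443). Its retention ratio was 0.153 ± 0.143 in WT and 6.68 ± 2.57 in KO (SD, n = 3). In KO the intron held more reads than the mean of its neighbouring exons. Reads of an overlapping or antisense transcript therefore cannot be separated from retention here. With 1 mutant line, other genome differences cannot be told apart from the mutation. This intron was the only one of 8612 tested that passed, with 232 introns at an unadjusted p under 0.05. Introns of the photosynthesis list, which was aimed at the light reactions and carbon fixation, shifted lower in KO as a group. The median of 77 introns in 40 genes was -0.28, against -0.04 over all introns. No single photosynthesis intron passed, and the list passed with camera (adjusted p = 0.0222; adjusted p = 0.949 with an estimated correlation). With 1 intron per gene its camera adjusted p was 0.515, and with fry on all its introns the adjusted p was 0.818. None of the other 14 lists with introns passed, and none of their introns passed over all introns or adjusted over the list alone. Their adjusted p was 0.71 for SR proteins, spliceosome components, FK506-binding proteins and cyclophilins, NAC and heat stress factors, chaperones, circadian clock and calcium signalling kinases. It was 0.784 for osmolyte synthesis, aquaporins, cytosolic ribosomal proteins and mRNA decay, and 0.906 for abscisic acid signalling, antioxidant enzymes and translation factors. The direction of the test and the sign of the median differ for abscisic acid signalling, translation factors and osmolyte synthesis. The call of the Os04t0587451 intron was lost in 7 of 13 alternatives, among them edgeR on the recovered reads, where 0 introns passed and 253 had an unadjusted p under 0.05. It was also lost without monosome WT P2 or P3 and no longer tested without any 1 of the KO libraries, and the photosynthesis list was lost without monosome WT P1, WT P3, KO P2 or KO P3.

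In the polysomes, the same question concerns transcripts under heavier translation. The introns with the smallest p leaned lower in KO, but none passed the test. Intron 3 of Os03t0599800, a reversibly glycosylated polypeptide of the kind used in cell wall synthesis, had a ratio of 0.0370 ± 0.0108 in WT and 0.00955 ± 0.00309 in KO (SD, n = 3), a log2 difference of -1.96. Intron 6 of Os03t0807400, a pentatricopeptide repeat protein of a family that processes organelle RNA, differed by -1.47. Intron 11 of Os01t0563000, an FKBP-type peptidyl-prolyl isomerase on chromosome 1 (21438306 to 21440963), had 0.150 ± 0.0181 in WT and 0.0839 ± 0.0134 in KO (SD, n = 3), a log2 difference of -0.84. Intron 3 of Os06t0206100, similar to Gb protein, went the other way by 1.26. The others were introns of Os09t0128600 (CMP/dCMP deaminase, -0.68), Os08t0436000 (nucleotide-binding protein, -1.03), Os03t0439800 (predicted protein, -0.92), Os01t0615300 (transferase, -1.30), Os09t0248000 (ethanol tolerance protein GEKO1, -0.66) and Os10t0100300 (NAD(P)-binding protein, -0.88). With limma, 0 of 6935 introns passed (smallest adjusted p = 0.758) and 432 had an unadjusted p under 0.05, and edgeR and DESeq2 also gave 0 (377 and 145 at an unadjusted p under 0.05). The FKBP-type intron passed adjusted over the list alone (limma adjusted p = 0.0377, 1 of 30 introns of its list), while 0 passed over all introns. No list passed. The lowest adjusted p was 0.171 for the circadian clock (median -0.38), then 0.174 for ribosomal proteins (median -0.03) and calcium signalling kinases (median -0.36), against a median of -0.11 over all introns. It was 0.554 for NAC and heat stress factors and 0.591 for aquaporins. It was 0.834 for chaperones and mRNA decay, and 0.94 for SR proteins, spliceosome components, FK506-binding proteins and cyclophilins, abscisic acid signalling, osmolyte synthesis, antioxidant enzymes, translation factors and photosynthesis. For SR proteins, abscisic acid signalling, osmolyte synthesis, chaperones, antioxidant enzymes and ribosomal proteins the test points up although the median is negative. Without the libraries labelled polysome WT P2 and P3, 0 introns passed, with a smallest adjusted p of 0.0621 and the remaining WT library assumed to vary like KO.

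The authors' deposited table marks its own selection, 180 monosome entries at 132 distinct positions and 100 polysome entries at 80. In the monosomes, 66 entries were higher and 114 lower in KO. Higher ones include intron 13 of Os01t0182600, the GIGANTEA ortholog of the circadian clock (ratio 0.0263 in WT and 0.0636 in KO), and intron 1 of Os02t0286200, a class 3 lipase (2.15 and 6.84). Lower ones include intron 1 of Os02t0802700, a monogalactosyldiacylglycerol synthase of chloroplast membranes (0.962 and 0.328), intron 1 of Os11t0158400, similar to digalactosyldiacylglycerol synthase 1 (2.12 and 0.873), and intron 1 of Os01t0764000, a glutathione S-transferase (0.165 and 0.0711). Some ratios lay above 1, as for the lipase and Os11t0158400, where reads of an overlapping or antisense transcript cannot be separated from retention. In the polysomes, 17 entries were higher and 83 lower, where the WT means include the doubted libraries labelled polysome WT P2 and P3. Lower ones include introns of 3 calcium signalling genes: intron 7 of Os07t0515100, calcium-dependent protein kinase isoform 2 (0.168 and 0.0693), intron 1 of Os07t0161600, a calcium-dependent kinase of the cold stress response (0.218 and 0.116), and intron 2 of Os04t0584600 (0.0898 and 0.0559). Intron 1 of Os06t0178900, the vacuolar pyrophosphatase Ovp2, was also lower (0.0596 and 0.0271), and introns of ribosomal proteins S19-3 (Os03t0424500, 0.0526 and 0.0954) and L5 (Os01t0896700, 0.0152 and 0.0230) were higher. These deposited p-values are unadjusted: after Benjamini-Hochberg adjustment over all introns the smallest was 0.991 in the monosomes and 0.917 in the polysomes. With limma, all 104 selected monosome introns that were tested pointed the same way, 65 had an unadjusted p under 0.05 and 1 passed. All 71 tested polysome introns pointed the same way, 69 had an unadjusted p under 0.05 and 0 passed. The authors selected these introns on ratios of the same libraries, so the shared direction and small unadjusted p are no separate evidence. With ratios centred on the median of each library, the authors' rule gave 32 higher and 31 lower polysome introns in place of 13 and 67, and 64 higher and 111 lower monosome introns in place of 53 and 78.

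**Figure D2:**
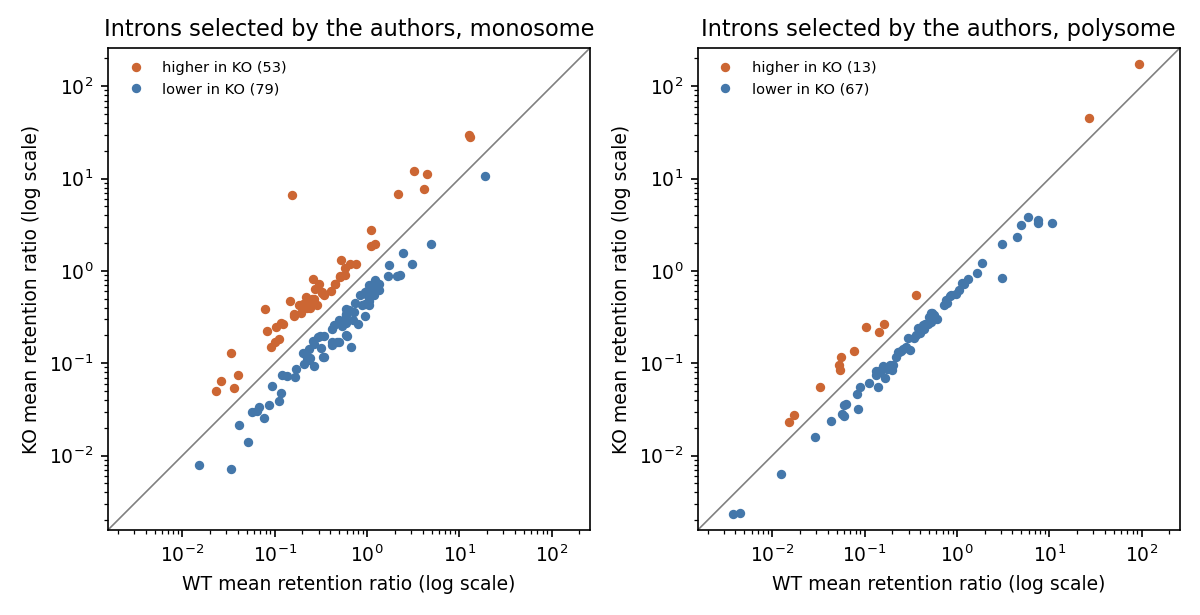
Mean retention ratio of the introns selected in the authors' deposited table, WT on the horizontal and KO on the vertical axis, both on log scales, for 132 monosome (left) and 80 polysome (right) positions; the line marks equal ratios. Points above the line are higher in KO and points below it lower, and in the polysomes most lie below.

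Whether the mutant's effect on introns differs between the fractions was tested directly. In 5100 introns measured in both, limma found 0 with a different KO effect, 181 had an unadjusted p under 0.05, and edgeR gave 0 (167). This test and the overlaps below use the doubted libraries labelled polysome WT P2 and P3. Within the fractions, 0% and 1.79% of simulated 2-fold intron changes were recovered in the monosomes and polysomes. The counts of 0 therefore do not show that the KO effects are alike. Of the authors' selected introns, 1 was lower in both fractions, intron 7 of Os07t0258400, which encodes the metal transporter OsNramp1 (0.237 in WT and 0.109 in KO monosomes, 0.258 and 0.143 in polysomes). The expected overlap was 0.415 among 3945 introns (Fisher's exact p = 0.343). In the higher direction 0 were shared (23 monosome and 9 polysome introns, expected 0.0525, Fisher's exact p = 1). In either direction 3 were shared against 0.894 expected (Fisher's exact p = 0.0591), and 2 of these went opposite ways, higher in KO monosomes and lower in KO polysomes. They are intron 8 of Os10t0461100, described as similar to a keratin (0.0232 and 0.0496 in monosomes, 0.0599 and 0.0352 in polysomes), and intron 4 of Os01t0702000, a DUF151 protein (0.325 and 0.598, 0.231 and 0.132). By gene, 1 was shared in the lower direction against 1.03 expected (Fisher's exact p = 1).

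Gene abundance in the monosomes asks which transcripts themselves were more or less common on single ribosomes of the mutant. A metallothionein gene had no reads in KO monosomes: Os05t0202800, similar to metallothionein-like protein 3B, a small cysteine-rich metal-binding protein, had 298, 75 and 198 reads in WT and 0 in all 3 KO libraries (at least 208-fold lower, limma adjusted p = 4.56e-05). Most of the 18 genes that rose lack a description of function. Among these, Os08t0240200 had 0 reads in WT and 316, 368 and 378 in KO (at least 323-fold higher), and Os03t0299700 was at least 292-fold higher. These folds use a floor of 3 reads over the WT group. Os01t0537250, a DUF3778 protein, rose from 1.12 ± 0.275 to 27.8 ± 5.63 CPM (SD, n = 3, log2 4.53, limma adjusted p = 3.6e-06), and Os10t0567900, an F-box protein interaction domain gene, by 3.71. Os11t0213000, a protein kinase domain gene, rose from 6.86 ± 0.218 to 28.4 ± 2.85 CPM (SD, n = 3, log2 2.03, limma adjusted p = 0.000317). Os04t0175600, an O-methyltransferase, rose by 1.72, and Os04t0543900, similar to glutamate dehydrogenase 2, which links nitrogen and carbon metabolism, rose from 27.8 ± 2.02 to 60.1 ± 6.45 CPM (SD, n = 3, log2 1.11, limma adjusted p = 0.0191). In all, 18 genes rose and 1 fell of 18515 tested, and edgeR called 22 and DESeq2 58. With 1 mutant line, other genome differences cannot be told apart from the mutation for any of these genes. The metallothionein gene was named by a rule set after the data were seen. The other described genes lay outside that rule and were named after their values were seen. The calls of Os04t0175600 and Os04t0543900 were each lost in 6 of 14 alternatives and that of Os10t0567900 in 3 of 14, and without monosome WT P2 the count was 81, without KO P1 12 and without KO P3 11.

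Among the gene lists in the monosomes, circadian clock genes shifted higher in KO, with a median log2 of 0.25 over 9 genes (camera adjusted p = 0.00528; adjusted p = 0.617 with an estimated correlation). Over all genes 0 clock genes passed, and 4 did adjusted over the list alone: Os02t0618200 (0.86), Os09t0532400 (0.52) and Os11t0157600 (0.59), which are pseudo response regulators of the clock, and Os01t0566100 (0.60), an ortholog of ELF3, a repressor of evening light signalling. Cytosolic ribosomal proteins shifted lower by a small amount, with a median of -0.07 over 249 genes and 0 passing (camera adjusted p = 0.0335; adjusted p = 0.918 with an estimated correlation). Of 16 SR protein genes, which guide splice site choice, Os02t0122800 passed adjusted over the list alone (0.73, limma adjusted p = 0.0169), and the list did not pass (adjusted p = 0.821). In the photosynthesis list Os02t0765900, similar to ferredoxin-nitrite reductase, an enzyme of nitrogen assimilation, passed adjusted over the list alone (2.77, limma adjusted p = 0.0158), and the list did not (0.921). The remaining lists had 0 genes past the test, over all genes and adjusted over the list alone. Their camera adjusted p was 0.326 for osmolyte synthesis, and 0.415 for FK506-binding proteins and cyclophilins, abscisic acid signalling and seed storage proteins, of which 3 genes were measured. It was 0.821 for chaperones and aquaporins, and 0.891 for spliceosome components, LEA proteins, NAC and heat stress factors, mRNA decay and root markers. It was 0.921 for antioxidant enzymes, translation factors and calcium signalling kinases. The median and the test differ in sign for LEA proteins and photosynthesis. Both list calls were lost without monosome WT P2, KO P1 or KO P3. With fry neither list passed (fry adjusted p = 0.475 for the circadian clock and 0.767 for ribosomal proteins). Of 10 splits of the monosome libraries, the real one included, 6 gave as many lists with camera.

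In the polysomes, the genes that separated the genotypes in the monosomes did not separate the labelled groups. The 10 genes that were on in KO monosomes, with at most 3 reads over the WT monosomes, had a median level of 113% of the KO polysome mean in the library labelled polysome WT P2 and 58.0% in WT P3. In the library labelled WT P4 they had 0 reads, as in monosome WT P1 and P3. Metallothionein-like 3B had 18, 287 and 630 reads in the libraries labelled polysome WT P2, P3 and P4, and 44, 13 and 6 in KO. Against this background, limma called 0 of 20337 genes, with 479 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 (486 and 431). The smallest p belonged to Os06t0250600, an outward Shaker potassium channel of guard cells (log2 1.01, 3.78 ± 0.134 CPM in WT and 7.73 ± 1.28 in KO, SD, n = 3). Among the others were 2 genes lower in KO, Os06t0101800, similar to NAC-domain protein 1-1 (-1.45), and Os10t0440100, a DP transcription factor (-0.84). None of them passed (adjusted p = 0.999). Without the libraries labelled polysome WT P2 and P3, a choice made after seeing the data, 11 genes were higher in KO, with the remaining WT library assumed to vary like KO. Of these, 7 had risen in the monosomes, which is no separate evidence, since both libraries were left out for their reads of such genes.

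**Figure D3:**
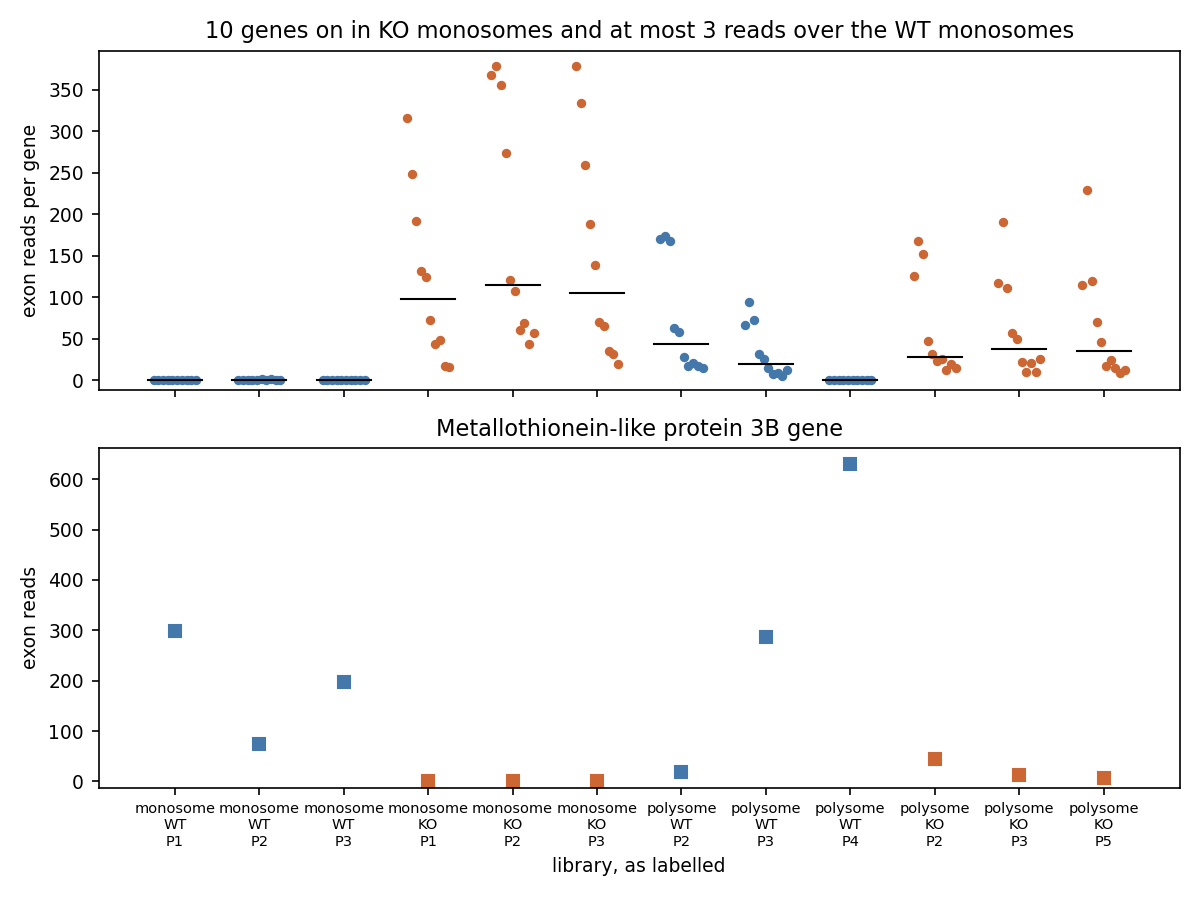
Exon reads in each of the 12 libraries, as labelled, for the 10 genes that were on in KO monosomes with at most 3 reads over the WT monosomes (top, points are genes and bars the median) and for the metallothionein-like 3B gene (bottom). The libraries labelled polysome WT P2 and P3 hold reads of the 10 genes, and WT P4 holds 0.

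No gene list passed in the polysomes. The lowest camera adjusted p was 0.0996 for aquaporins, the water channels (median log2 0.19 over 10 genes), and 0.232 for osmolyte synthesis (median 0.14). It was 0.443 for mRNA decay and root markers, 0.527 for ribosomal proteins, and 0.689 for circadian clock and seed storage proteins. It was 0.90 for spliceosome components, LEA proteins and translation factors, and 0.92 for SR proteins. It was 0.914 for FK506-binding proteins and cyclophilins, abscisic acid signalling, NAC and heat stress factors, chaperones, antioxidant enzymes, photosynthesis and calcium signalling kinases. All lists had 0 genes past the test, over all genes and adjusted over the list alone, and the median and the test differ in sign for chaperones and antioxidant enzymes. Without the libraries labelled polysome WT P2 and P3, LEA proteins and osmolyte synthesis were higher in KO (camera adjusted p = 0.0313 each; adjusted p = 0.786 each with an estimated correlation). That fit has 1 WT library, which is assumed to vary like KO. The KO effect on genes differed between fractions for 0 of 20977 genes by limma (690 at an unadjusted p under 0.05), a test added after the data were seen. Some genes passed it without the library labelled polysome WT P4 or with the replicate block, as given with the processing.

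The housekeeping genes of the authors' deposited table were measured in all 12 libraries. In reads scaled to library size, log2 differences of KO from WT in the monosomes were -0.28 for actin OsACT1, -0.31 for OsGAPDH and -0.34 for ubiquitin OsUBQ3 (exact permutation p = 0.1, 0.2 and 0.2, n = 3). In the polysomes they were 0.20, 0.13 and 0.04 (exact permutation p = 0.3, 0.6 and 0.9, n = 3). With TMM scaling the monosome differences were -0.08, -0.12 and -0.09 and the polysome differences 0.14, 0.05 and -0.04, so OsUBQ3 in the polysomes changes sign with the scaling.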

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

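The tests of the differences and of the explanations in this part were chosen after the results were seen, except that the outcome expected without polysome KO P5 was written before that value was seen.

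The KO effect on the share of reads in Rubisco large subunit copies differed between the fractions by -11.9 percentage points, from 6.30 in the monosomes to -5.61 in the polysomes (exact permutation p = 0.01 over 400 relabellings, adjusted over 5 measures 0.0375). Without polysome KO P5 the polysome effect was -1.74 in place of -5.61 and the difference -8.04 (exact permutation p = 0.015). Without the doubted libraries labelled polysome WT P2 and P3, the difference was -13.7 (exact permutation p = 0.113).

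The KO effect on actin OsACT1, in reads scaled to library size, differed by 0.49 on the log2 scale, from -0.28 to 0.20 (exact permutation p = 0.015, adjusted 0.0375). The polysome effect was 0.10 without polysome KO P5 and 0.11 without the library labelled polysome WT P4, and it was 0.39 without those labelled WT P2 and P3. That scale moves with the Rubisco share, and with TMM scaling the OsACT1 values were -0.08 and 0.14.

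The 10 genes that were on in KO monosomes also had reads in the libraries labelled polysome WT P2 and P3. A low level of exchanged sequencing tags over all polysome WT libraries is argued against. The lowest median level in the libraries labelled polysome WT P2 and P3 was 58.0% of KO polysomes, while that labelled polysome WT P4 had 0 reads. An exchange of the tags of whole libraries was not covered by this test and stays open. RNA of KO plants in the library labelled polysome WT P2 could give the median level of 113% found there, and RNA of KO plants making up part of the library labelled polysome WT P3 could give the 58.0% found there. WT seed that carried the KO-type genes cannot be told apart from this: 0 monosome WT libraries had a median level above 10 percent of KO, and the seed used for each fraction is not given in the sources used here. No sample was reassigned.

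The same 10 genes, with the metallothionein gene that had 0 reads in KO monosomes, make 11 genes on in the monosomes of 1 genotype and at or near 0 reads in those of the other; KO polysomes held 44, 13 and 6 metallothionein reads. A single genome segment around the mutated gene is argued against, since these genes lie on 6 chromosomes. Other differences between the genomes of the KO line and the WT plants cannot be told apart from an effect of the mutation. The design has 1 mutant line, so this holds for these 11 genes and for every other difference of KO from WT.

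The introns selected by the authors' rule leaned lower in KO, with 59.5% lower in the monosomes and 83.8% in the polysomes. In the monosomes the lean remained after each library was centred on its median, with 63.4% lower (95% Wilson interval 56.1 to 70.2). The introns share the same libraries, so this interval does not cover the spread between libraries. Whether a shift of all retention ratios in some monosome libraries is the whole cause therefore cannot be told. Without monosome WT P2 the rule gave 294 introns in place of 131, of which 84.0% were lower. In the polysomes such a shift cannot be told apart from an effect of the genotype. The WT group there includes the doubted libraries labelled polysome WT P2 and P3, so the polysome lean is no clean comparison of the genotypes. Without KO P5, the library with the most distant median, 71.1% were lower (95% Wilson interval 56.6 to 82.3, 45 introns in place of 80). The lean thus remained without that library, but this interval does not cover the spread between libraries either. After centring 49.2% were lower, and centring would remove a shift that goes with the genotype as well as one of single libraries.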

How the results depend on the processing

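Chosen after the data were seen were the polysome against monosome comparisons, the fraction test on genes, centring, the deposited scaling factors, the Rubisco alternative, leaving out both libraries labelled polysome WT P2 and P3, the leave-outs of the authors' rule, and the leave-outs and uncorrected word matches of the lists. Over the comparisons, 176 alternative values stayed within the limits set and 61 moved beyond them; over single genes and introns and the authors' rule, 237 kept their call or stayed within the limits, 44 lost the call, and 2 counts of the authors' rule moved. None of these single genes and introns changed direction. Where a cause is not named below, the cause was not tested.

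Introns changed in the monosomes, 1 in the report, numbered 0 with edgeR, with RLE size factors in edgeR, with all 12 samples in 1 fit, with a minimum of 30 reads, with the pseudocount 0.1 times and with no filter, and 3 with intron reads alone. Leaving out 1 library gave 0 to 1. Genes changed in the monosomes, 19 in the report, numbered 58 with DESeq2, and 11 to 81 with 1 library left out. Leaving out both libraries labelled polysome WT P2 and P3 gave 11 genes in the polysomes in place of 0, and, for WT polysomes against monosomes, 508 introns in place of 2898 and 2371 genes in place of 8988, with the lone WT library assumed to vary like the other groups. With no filter these introns numbered 12406 in KO and 5377 in WT, where more introns are tested. Leaving out 1 library gave 2171 to 3243 in KO and 1709 to 3090 in WT. Genes with a different KO effect between fractions numbered 0 to 10, the highest without the library labelled polysome WT P4. The intron share difference in the polysomes was -0.400 percentage points with Rubisco copies left out, in place of -0.0752, and 0.0290 without the library labelled polysome WT P4. Of the authors' own calls, 1 intron overlapped between fractions in the same direction and 3 in either direction; by gene, 1 overlapped in the same direction.

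With an estimated correlation, 0 lists passed in any comparison. With 1 intron per gene, 0 intron lists passed in the monosomes and 0 in WT polysomes against monosomes. Without both libraries labelled polysome WT P2 and P3, 2 gene lists passed in the polysomes and 2 intron lists in WT polysomes against monosomes. Leaving out 1 library gave 0 to 1 intron lists in the monosomes, 0 to 1 in KO polysomes against monosomes and 1 to 3 in WT, and 0 to 2 gene lists in the monosomes and 0 to 1 in the polysomes.

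The sources do not say whether the P numbers of the columns pair the samples, and the data leave it open: deviations of genes correlated at 0.118, 0.343 and 0.0991 between same-numbered monosome libraries and at 0.360 and 0.0688 in the polysomes, but monosome WT P1 correlated best with KO P3 (0.146). By chi-square per degree of freedom of gene reads, 3 of the 5 same-numbered pairs are each other's closest library of the fraction: P2 of the monosomes (3.78) and P2 and P3 of the polysomes (1.67 and 1.45), the last 2 with the doubted libraries labelled polysome WT P2 and P3. The replicate block moved genes from 19 to 55 in the monosomes and from 0 to 3 in the polysomes, genes with a different KO effect between fractions from 0 to 11, and intron lists in WT polysomes against monosomes from 1 to 2. Restricting the share to nuclear chromosomes moves nothing, since the tables hold no others, and scaling cannot move a ratio within a library. The read minimum limits which introns are tested: with no filter, 89277 monosome introns were tested, against 8612 with at least 10 reads. Depth itself was not varied.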

Other observations

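The polysome against monosome comparisons, the difference of gene effects between fractions, and the tests by other splits of the samples, except those of the gene lists, were chosen after the results were seen.

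Within KO, the relative abundance of genes differed between polysomes and monosomes. Nicotianamine synthases, which make a metal chelator, were among the genes with the largest differences: Os03t0307300 was higher in polysomes by 5.24 on the log2 scale and Os03t0307200 by 4.67. Of 18 gene lists 9 passed, all of them with an adjusted p = 0.284 to 0.29 with an estimated correlation, and another split of the libraries gave up to 7. Cytosolic ribosomal proteins were higher in polysomes (144 higher and 26 lower of 253, median 0.68, camera adjusted p = 1.77e-08), and so were photosynthesis genes (52 and 14 of 88, median 0.87, 7.45e-05), such as photosystem I subunit VI Os05t0560000 (2.53) and plastocyanin Os06t0101600 (1.79). Aquaporins (9 and 0 of 10, median 1.75, 0.000344) include Os02t0666200 (2.54) and Os07t0448800 (2.45). Antioxidant enzymes (69 and 23 of 149, median 0.61, 0.000974) include 2-Cys peroxiredoxin Os02t0537700, with 56.1 ± 0.981 CPM in monosomes and 367 ± 57.9 in polysomes (SD, n = 3), and catalase Os02t0115700 (2.03). LEA proteins (8 and 1 of 10, median 2.06, 0.0182) include dehydrin Os02t0669100 (2.45), and FK506-binding proteins and cyclophilins (20 and 4 of 45, median 0.49, 0.0188) include cyclophilin Os02t0121300 (2.92). Seed storage proteins (3 and 0 of 4, median 1.46, 0.0436) and root markers (3 and 0 of 3, median 2.10, 0.0358) were higher too, with glutelin Os01t0111900 (1.97) and RCc3-like Os04t0554800 (2.48). Circadian clock genes were lower in polysomes (0 higher and 5 lower of 9, median -0.83, 0.0188), among them PRR73-like Os03t0284100 (-1.44) and Os11t0157600 (-1.35). The SR list did not pass (0.242), although SR12-like Os12t0516700 was lower by -2.70. The other 9 lists had a camera adjusted p from 0.0914 to 0.769. In all, limma called 5215 genes higher and 4986 lower in polysomes of 19962 tested, and edgeR called 10136. Reads recovered from the monosome and polysome tables undo their separate scaling. TMM scaling takes most genes as unchanged, so these values are relative abundances within a fraction, here and in WT. The near-even counts of higher and lower genes follow in part from that scaling.

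In WT, 4 of these lists passed, all higher in polysomes: ribosomal proteins (131 higher and 25 lower of 254, camera adjusted p = 1.38e-07), photosynthesis (47 and 12 of 88, 3.04e-05), antioxidant enzymes (65 and 18 of 145, 0.000301) and aquaporins (9 and 0 of 10, 0.000612). With an estimated correlation their adjusted p = 0.253, 0.253, 0.101 and 0.253, and another split of the libraries gave up to 5 lists. Cyclophilin Os02t0121300 was higher by 2.69, and ferredoxin-like Os03t0659200 was lower by -2.82. The other 14 lists had a camera adjusted p from 0.0535 to 0.74. In all, limma called 4467 genes higher and 4521 lower of 19845 tested, edgeR called 9071, and without the libraries labelled polysome WT P2 and P3 the count was 2371.

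Most introns that passed had fewer reads relative to their neighbouring exons in polysomes than in monosomes. In KO, 3563 introns were lower and 138 higher of 8133 tested with limma, and in WT 2778 were lower and 120 higher of 7997, in all 2898, against 508 without both libraries labelled polysome WT P2 and P3. Intron 1 of aquaporin Os07t0448800 was lower by -5.52 in KO and -5.46 in WT, intron 1 of photosystem II 10 kDa protein Os07t0147500 by -3.17 and -3.55, and intron 3 of GIGANTEA Os01t0182600 by -2.57 in KO. Intron 1 of isoamylase-type Os09t0469400 was higher by 2.73 in KO and 2.64 in WT. Photosynthesis introns were lower as a list in WT (55 of 88, median -1.78, camera adjusted p = 0.0019; adjusted p = 0.828 with an estimated correlation and 0.167 with 1 intron per gene). In KO the same list had 60 of 89 introns lower and a median of -1.52, and did not pass (camera adjusted p = 0.0829; adjusted p = 0.802 with an estimated correlation), though it passed in 5 of 6 fits with 1 library left out. No other intron list passed in KO. With ratios centred on the median of each library, the split was 2589 higher and 1665 lower in KO, and 1846 and 1407 in WT. The excess of lower introns thus rests on a shift over all introns (median log2 -0.87 in KO and -0.73 in WT). Centring would remove a shift that goes with the fraction as well as one of single libraries, so it does not tell these apart. Without 1 library the count fell below 3701 to 2336 (KO P1 of the monosomes) or 2171 (KO P3 of the monosomes). In WT it fell below 2898 to 1775 or 1709 without monosome P1 or P3, and to 1904 or 1864 without the libraries labelled polysome P2 or P3.

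Each group comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For introns, 1 split gave as many calls in the monosomes (real value 1, highest other 0), 10 in the polysomes (0, highest other 1), 1 in KO polysomes against monosomes (3701, highest other 0) and 1 in WT (2898, highest other 0). For genes, 1 split gave as many in the monosomes (19, highest other 1), 10 in the polysomes (0, highest other 0), 1 in KO polysomes against monosomes (10201, highest other 0) and 1 in WT (8988, highest other 0). For intron lists these were 2 in the monosomes (1, highest other 2), 10 in the polysomes (0, highest other 0), 10 in KO polysomes against monosomes (0, highest other 0) and 1 in WT (1, highest other 0). For gene lists they were 6 in the monosomes (2, highest other 6), 10 in the polysomes (0, highest other 1), 1 in KO polysomes against monosomes (9, highest other 7) and 4 in WT (4, highest other 5). The authors' rule gave as many introns in 8 monosome splits (131, highest other 354) and in 2 polysome splits (80, highest other 120). The monosome split with 354 puts WT P1, WT P3 and KO P3 together, the 3 monosome libraries with the highest intron shares, and points to a structure of the samples. For the difference of KO effects between fractions, 100 of 100 drawn splits gave as many introns (0, highest other 0) and 100 of 100 as many genes (0, highest other 23). Wherever the real count is 0, every split gives as many, so such counts decide nothing.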
